A study of Bacillus subtilis with 4 samples.

How the data were processed

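*Bacillus subtilis* W168 wild type and *sigA* (G336C) cells were grown in LB to an OD600 of 0.4, RNA was extracted with a column kit and treated with DNase, and cDNA from 20 µg of total RNA was labelled with Alexa Fluor 555 or 647, per the labels' protocols. Per the labels, 2 replicates were each hybridised on a direct array (wild type in 555, mutant in 647) and on a dye-swapped array of the same RNA preparation, 4 arrays in all. The series' design text also speaks of biological triplicates, whereas the labels number 2 replicates, and 2 was used.

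The authors deposited log2 ratios of the channels of each array, with 4116 lines per array, of which 10 are controls foreign to the culture and 4106 carry a gene symbol. That they are log2 ratios was read from the deposited values: 2 to the power of the value lay within 0.02 of a whole hundredth, counted in hundredths, for 95.8% to 98.4% of values per array, and the lowest ratio was 0.01. Scanner, background correction, normalization, filters and which channel is the numerator are not given in the sources used here. Spot intensities were not used here, so dim spots could not be filtered and the signal behind each ratio is unknown. Symbols were used as deposited; 3036 of the 4106 matched the RefSeq table of assembly ASM904v1, and no coordinates are given because the arrays' build is not given in the sources used here.

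Control lines were left out. By the rule fixed for this, the dye-swapped columns were taken as already turned and no sign was changed, because each direct array correlated above 0 with the dye-swapped array of its own RNA. That correlation was weak (r = 0.0666 and 0.120), and it was -0.0252 between the direct array of replicate 1 and the dye-swapped array of replicate 2. The 2 arrays of a replicate were averaged, so that the dye effect cancels and n is 2, and the averages were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over 4052 genes with 4 values and a threshold of 0.05; the moderated fit had 1.96 degrees of freedom. With 2 replicates an exact two-sided sign-flip test cannot go below 0.5. The series' design text calls the RNA preparations independent, and p-values measure the spread between the 2 replicates. Lists of 981 textbook symbols in all, of which 860 matched as deposited, were tested with limma's camera at a preset correlation of 0.01 and with an estimated one, with Benjamini-Hochberg adjustment over the 38 lists that had at least 4 measured genes; 1 list, of Zur zinc uptake genes, had fewer and was not tested. The gene and list tests were tested on simulated data with known changes.

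The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named *sigA*, then in each direction the 12 genes with the largest mean among those past the gene test with the same sign on all 4 arrays, filled up with the largest same-sign means where fewer passed (here all), then up to 4 members with the largest absolute mean of each list described, and *glpT* and *glpQ* in any case. Restricting the last part to the 17 lists past camera was chosen after values for members of all lists had been seen: with all lists, 162 genes would be named in place of 83, 34 gene values would turn in sign under an alternative in place of 10, and 33 of 207 results would have 1 array standing apart in place of 14 of 128. Genes named beyond the rule, such as *rocD*, *sdhB*, *argB*, *argC*, *yclO*, *yclP*, *yclQ*, *pyrB*, *glpP* and *atpF*, were chosen after their values were seen. Alternatives covered how arrays are combined, scaling between arrays, variance moderation, missing values, thresholds, each replicate and orientation left out, and other tests and memberships of the lists. Leaving out genes at the lowest ratio or 0, leaving out the dye-swapped array of replicate 2, a replicate block without a dye term and 110 list members matched by older symbols, known from textbooks, were added after the data were seen.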

Results

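Transcript levels of *Bacillus subtilis* W168 were compared between the wild type and a strain carrying the G336C allele of *sigA*, the gene of the primary sigma factor, which directs RNA polymerase to most promoters in growing cells. Both strains had been grown in LB broth to an OD600 of 0.4. The RNA of both strains was hybridised together on 4 two-channel arrays. Each of 2 biological replicates was run on a direct array (mutant in Alexa Fluor 647) and on a dye-swapped array (mutant in Alexa Fluor 555). Values were available for 4106 genes, of which 4052 had a value on all 4 arrays, and the number of arrays limits the precision. The arrays' median log2 ratios were 0.04 and 0.00 in replicate 1 and 0.00 and -0.45 in replicate 2, direct array first. A positive log2 ratio likely stands for a higher level in the mutant. This direction rests on the mutant being channel 2 of the direct arrays, on the dye-swapped columns being taken to run the same way already, and on the lower *glpT* and *glpQ* levels known for this allele. These genes are therefore no independent evidence of it. If the direction were wrong, every sign given here would turn. Means are given ± SD over the 2 replicates (n = 2), each replicate being the mean of its direct and dye-swapped array.

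The first question was which genes differ in level between the *sigA* mutant and the wild type. Among genes of one sign on all 4 arrays, those of arginine breakdown held 5 of the 12 highest means, the top one included. Mean log2 ratios were 10.11 ± 2.47 for *rocB*, 9.93 ± 0.92 for *rocG* (catabolic glutamate dehydrogenase), 6.64 ± 1.68 for *rocE* (an amino acid permease), 6.28 ± 0.61 for *rocA* and 5.38 ± 0.12 for *rocF* (arginase). Next to these 5 *roc* genes, the 12 highest means included *paiA* (7.65 ± 1.26) and its neighbour *paiB* (5.05 ± 0.13), *ylbA* (5.56 ± 0.70), *ycbK* (5.14 ± 0.72), the SPbeta prophage gene *bhlA* (4.91 ± 0.01), *ysfD* (4.62 ± 0.28) and *ysxD* (4.13 ± 0.00). The 12 lowest means included those of the surfactin synthetase genes *srfAB* (-5.36 ± 1.81) and *srfAC* (-4.55 ± 1.55), of *pyrF* (-4.84 ± 0.21, pyrimidine synthesis), of the spore coat genes *cotY* (-4.77 ± 0.30), *cotZ* (-4.74 ± 1.28) and *cotG* (-4.48 ± 3.06), and of *glpD* (-4.67 ± 0.67, glycerol-3-phosphate dehydrogenase). The others were *yxaF* (-4.75 ± 0.85), *purQ* (-4.37 ± 3.21), *yhbI* (-4.34 ± 2.55), *yhaO* (-4.22 ± 2.31) and *opuCC* (-4.21 ± 2.74). A small SD over the replicates can hide a wide spread between the arrays of one replicate. On the direct and dye-swapped array of replicate 1 and then of replicate 2, *ysxD* stood at 4.02, 4.25, 6.69 and 1.58. On the same arrays *cotY* stood at -3.32, -6.64, -2.47 and -6.64. The gene carrying the allele, *sigA* itself, had a mean log2 ratio of -0.12 ± 0.07. The glycerol-3-phosphate permease gene *glpT* (-2.87 ± 0.15) and the phosphodiesterase gene *glpQ* (-1.83 ± 0.59) were below 0 on all 4 arrays.

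None of these genes passed the gene test. Limma called 0 of 4052 genes, with a lowest adjusted p of 0.258, while 764 genes had an unadjusted p under 0.05 (387 higher, 377 lower) where chance gives 202.6. The same limma fit on 1 simulated pair of replicates recovered 0% of the genes changed by 1, 2, 4 or 8 on the log2 scale. After quantile normalization that fit called 480 genes (135 higher, 345 lower). With the 4 arrays treated as independent and a dye term, limma called 306 genes (180 higher, 126 lower), a count that takes arrays of the same RNA for replicates.

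By sign alone, 1719 genes (42.4%) had the same sign on all 4 arrays, 691 positive and 1028 negative. Independent arrays would give 12.5%, which is not the share without any change here, because the arrays share RNA and dye orientations. Direct and dye-swapped arrays opposed each other in both replicates for 482 genes (11.9%), and the replicates opposed each other in both orientations for 144 (3.55%). Of the genes with one sign, 280 had a mean log2 ratio of at least 1, as did the *roc* genes named above, and 509 had a mean of -1 or less. These counts moved with the arrays used, and a pair of arrays shares a sign more easily: 495 and 385 in replicate 1 alone, 300 and 882 in replicate 2 alone, 533 and 675 on direct arrays, and 405 and 957 on dye-swapped arrays. At least 1 array stood at the lowest ratio in the files, 0.01, for 130 of the 509 genes and for 10 of the 12 genes with the lowest means, *pyrF* and *glpD* being the exceptions. Such values bound the ratio and do not measure it. High ratios also varied between arrays. Over the 4 arrays *rocB* ran from 5.73 to 12.56, *rocG* from 7.30 to 11.99, *paiA* from 3.99 to 10.03 and *rocA* from 3.39 to 8.31. By contrast, *rocF* stayed between 5.12 and 5.52. Spot intensities were not used, so how exact the high ratios are is unknown.

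**Figure D1:**
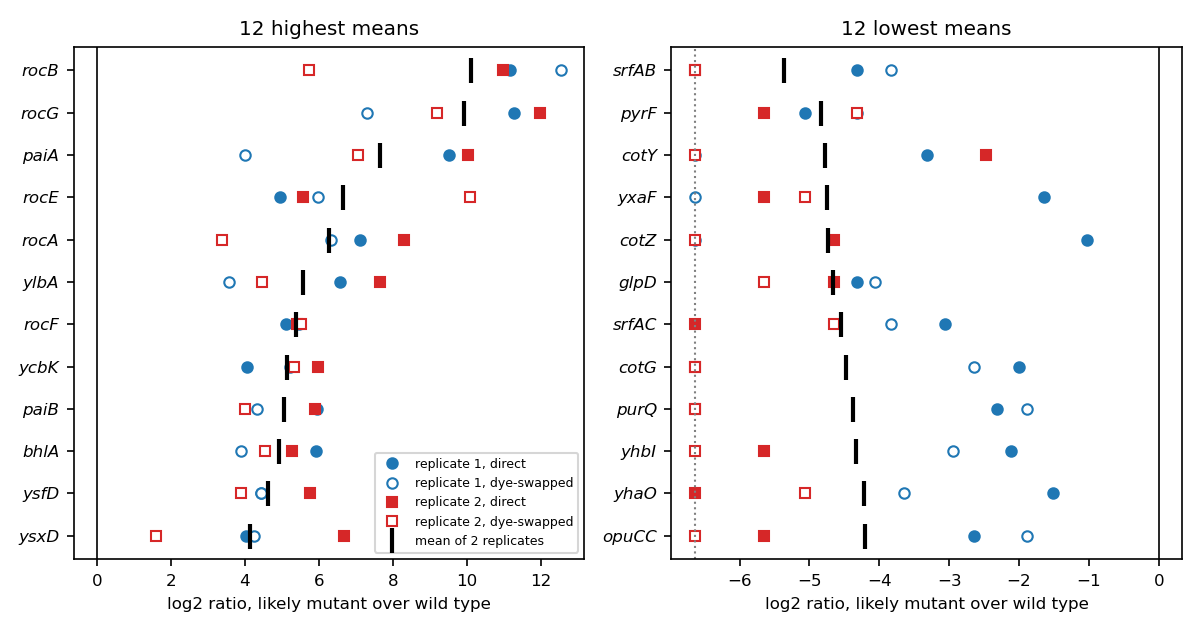
Log2 ratio (x axis, likely mutant over wild type) on each of the 4 arrays for the 12 genes with the highest and the 12 with the lowest mean among genes of one sign on all arrays; circles are replicate 1, squares replicate 2, filled symbols direct and open symbols dye-swapped arrays, bars the mean of 2 replicates, and the dotted line the lowest ratio in the files. All values of the 12 highest genes lie at 1.58 or above, and 10 of the 12 lowest genes have a symbol on the dotted line.

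The second question was which regulons and pathways shifted as groups against all other genes. Of 38 lists tested with limma's camera at a preset correlation, 17 passed, 10 upward and 7 downward. With the correlation between genes estimated from the 2 replicates, 0 of the 17 passed, the lowest adjusted p being 0.808. That form of camera rests on 1 residual degree of freedom, so hardly any list could pass and it decides little. For purine biosynthesis the estimate, -0.067, lay below the preset 0.01, yet the unadjusted camera p went from 1.42e-05 to 0.135. Whether the preset value is too low stays open. Members of one list can move together, so counts of members are not counts of independent results. List medians are given relative to the median of all genes, -0.26, since scaling the arrays alike moved that median by 0.11. No member of any list passed the test over all genes.

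The TCA cycle, carbon catabolite and arginine lists rose. The TCA cycle list rose by a relative median of 1.59 (adjusted p = 7.95e-05, adjusted p = 0.808 with an estimated correlation). Of its 12 measured genes, 9 passed adjusted over the list alone, 8 upward and 1 downward. Those upward included *odhB* (2.51 ± 0.32) and *odhA* (2.01 ± 0.25) of 2-oxoglutarate dehydrogenase. They also included *sucD* (1.78 ± 0.06) and *sucC* (1.68 ± 0.01) of succinyl-CoA synthetase. The 1 downward was *sdhB* (-1.68 ± 0.08) of succinate dehydrogenase. The other genes of that enzyme, *sdhA* (0.30 ± 0.32) and *sdhC* (0.03 ± 0.20), had mixed signs over the arrays. Its genes therefore did not fall together. Genes under carbon catabolite control rose by 0.84 (adjusted p = 2.20e-06, adjusted p = 0.808 with an estimated correlation). Among the 63 measured, 25 were positive and 5 negative on all 4 arrays and 0 passed adjusted over the list alone: the ribose genes *rbsD* and *rbsA* stood at 3.83 ± 0.19 and 3.10 ± 0.28, the mannose genes *manA* and *manP* at -3.91 ± 0.22 and -3.15 ± 0.13. The arginine list rose by 0.82 (adjusted p = 0.00255, adjusted p = 0.808 with an estimated correlation). Here 6 of 17 genes passed adjusted over the list alone, all upward and all for arginine breakdown: *rocA*, *rocB*, *rocE*, *rocF*, *rocG* and *rocD* (3.78 ± 0.79). The breakdown gene *rocC* and the regulator gene *rocR* were also measured and did not pass. The biosynthetic genes went both ways, *argC* at 1.0 ± 0.31 and *argB* at -0.76 ± 0.26.

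The Fur list of iron uptake genes rose by 0.88 (adjusted p = 0.00166, adjusted p = 0.808 with an estimated correlation). Of 23 genes, 7 passed adjusted over the list alone, and they split by transporter. The bacillibactin uptake genes *feuA* (4.01 ± 0.25), *feuB* (2.72 ± 0.20) and *feuC* (3.10 ± 0.14) were higher, and the petrobactin uptake genes *yclN* (-2.33 ± 0.33), *yclO* (-1.93 ± 0.26), *yclP* (-1.74 ± 0.23) and *yclQ* (-1.76 ± 0.07) lower. The SPbeta prophage list rose by 0.54 (adjusted p = 0.00166, adjusted p = 0.876 with an estimated correlation). Among its 51 genes, 11 were positive and 1 negative on all arrays and 0 passed adjusted over the list alone: besides *bhlA*, the largest means were *sunA* (3.93 ± 0.21) and *sunT* (3.0 ± 0.01), for the bacteriocin sublancin and its export, and *yonH* (3.15 ± 1.20), which was negative on 1 array. The relative median was 0.88 in replicate 1 and 0.22 in replicate 2.

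The ribosomal protein, aminoacyl-tRNA synthetase and ATP synthase lists fell. Ribosomal protein genes fell by a relative median of 0.55 (adjusted p = 7.58e-07, adjusted p = 0.876 with an estimated correlation). Of 51 measured, 43 were negative and 1 positive on all 4 arrays, with *rplF* at -1.35 ± 0.18, *rpmD* at -1.29 ± 0.15, *rplR* at -1.24 ± 0.21 and *rpsK* at -1.17 ± 0.15, and 0 passed adjusted over the list alone. The relative median was -0.97 in replicate 1 and -0.24 in replicate 2. Aminoacyl-tRNA synthetase genes, which charge tRNAs, fell by 0.94 (adjusted p = 1.29e-05, adjusted p = 0.808 with an estimated correlation). Of 23 genes 21 were negative on all arrays and 0 passed adjusted over the list alone, the lowest means being those of *thrZ* (-3.25 ± 3.38), *tyrZ* (-2.66 ± 2.43), *alaS* (-2.59 ± 2.37) and *valS* (-1.94 ± 0.85). These low means came mostly from replicate 2, at -5.64, -4.38, -4.27 and -2.54 in that order. In replicate 1 the same genes stood at -0.86, -0.95, -0.91 and -1.34. The ATP synthase list fell by 0.79 (adjusted p = 0.000300, adjusted p = 0.828 with an estimated correlation), and 9 of its 9 genes passed downward adjusted over the list alone, from *atpF* (-0.92 ± 0.16) to *atpD* (-1.53 ± 0.06). The correlation between its genes was estimated at 1, from 1 residual degree of freedom, against the preset 0.01. The 9 genes are therefore not 9 independent results. Against random lists the adjusted p of the ATP synthase list was 0.187, the highest over its alternatives apart from the estimated correlation, and the lowest was 2.96e-05.

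Purine biosynthesis genes fell by 1.33 (adjusted p = 0.000108, adjusted p = 0.808 with an estimated correlation). Of 16 genes, 9 passed downward adjusted over the list alone, among them *purA* (-2.25 ± 0.05) and *purF* (-1.85 ± 0.46). The genes *purQ* and *pbuG* (-3.26 ± 1.63) had lower means and did not pass. Pyrimidine biosynthesis genes fell by 1.22 (adjusted p = 0.00166, adjusted p = 0.808 with an estimated correlation). All 8 were negative on all arrays and 3 passed adjusted over the list alone, *pyrF*, *pyrAA* (-2.12 ± 0.24) and *pyrB* (-1.41 ± 0.12), while *pyrR* stood at -2.79 ± 3.21 and *pyrK* at -1.55 ± 0.57. The relative median was -1.64 in replicate 1 and -0.80 in replicate 2. The glycerol list fell by 1.11 (adjusted p = 0.00205, adjusted p = 0.808 with an estimated correlation). All 6 genes were negative on all arrays, and *glpD*, *glpT*, *glpQ*, *glpF* (-0.90 ± 0.07) and *glpP* (-0.90 ± 0.00) passed adjusted over the list alone, 5 of 6. Against random lists the adjusted p was 0.121, the highest over its alternatives apart from the estimated correlation, and the lowest was 0.000903. The relative median of the glycerol list was -1.62 in replicate 1 and -0.72 in replicate 2. The SOS list of DNA damage genes fell by 0.85 (adjusted p = 0.0206, adjusted p = 0.876 with an estimated correlation). Of 10 genes 8 were negative on all arrays and 0 passed adjusted over the list alone, with *uvrC* at -2.32 ± 1.82, *uvrB* at -1.55 ± 0.76 and *ruvA* at -1.42 ± 0.91. The mean of *yneA* (-1.71 ± 0.30) hides a change of sign, from -5.64 on the direct to 2.64 on the dye-swapped array of replicate 1. The SOS call was lost against random lists, without genes at the lowest ratio or 0 and with a dye term, its adjusted p over the alternatives apart from the estimated correlation running from 0.0142 to 0.117.

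The SigB, SigX, SigM and SigD regulons and the wall teichoic acid list rose, with 0 members past the threshold adjusted over the list alone in each. The relative medians of replicates 1 and 2 were 0.40 and 0.78 for SigX, 0.26 and 0.69 for SigM, 0.08 and 0.61 for SigD, and 0.25 and 0.80 for the teichoic acid list. The SigB general stress regulon rose by 0.48 (adjusted p = 0.00166, adjusted p = 0.808 with an estimated correlation), with 29 of 101 genes positive and 6 negative on all arrays. Its relative median was 0.09 on the direct and 0.75 on the dye-swapped arrays. *ywsB* (2.62 ± 0.27) and *yfhD* (2.37 ± 1.04) were its highest, *yqhA* (-2.63 ± 3.69) and *yxkO* (-2.28 ± 3.64) its lowest means. Both low means came from replicate 2, and *yxkO* stood at 0.30 in replicate 1. The SigX regulon rose by 0.62 (adjusted p = 0.00205, adjusted p = 0.808 with an estimated correlation), with *yjbC* at 1.52 ± 0.20, *rapD* at 1.19 ± 0.13, *lytR* at 0.99 ± 0.10 and *yfhO* at -0.95 ± 1.91, the last from -5.06 on 1 array. In this regulon 10 of 18 genes were positive on all arrays. The SigM regulon rose by 0.61 (adjusted p = 0.0109, adjusted p = 0.808 with an estimated correlation). Of 35 genes 9 were positive and 5 negative on all arrays. Besides *yjbC*, its largest means were *yhdL* (-1.63 ± 1.59), *murF* (-1.59 ± 2.31) and *yhdK* (1.24 ± 2.05). Each of these 3 had mixed signs or zeros and its mean came mostly from the dye-swapped array of replicate 2. Without that array *murF* turned to 0.13 and *yhdK* to -0.10. The motility and chemotaxis genes of SigD rose by 0.39 (adjusted p = 0.00423, adjusted p = 0.876 with an estimated correlation), 18 of 54 being positive and 5 negative on all arrays. Of its largest means, *epr* stood at 1.39 ± 0.64, *tlpC* at 1.51 ± 1.25, *tlpA* at -1.33 ± 1.83 and *cheC* at -1.64 ± 2.47. The signs of *tlpC* and *cheC* differed between arrays, and *cheC* stood at 0.11 in replicate 1. Wall teichoic acid and D-alanylation genes, which build and charge cell wall polymers, rose by 0.57 (adjusted p = 0.00964, adjusted p = 0.808 with an estimated correlation). Of 19 genes 8 were positive on all arrays, among them *lytR*, *tagE* (0.70 ± 0.04) and *tagA* (0.67 ± 0.13), and 2 negative, among them *tagB* (-0.71 ± 0.02). A member matched only by its older symbol, *yhxB*, is not among the 19 and stood at -2.68 ± 0.02. With older symbols the list had 24 genes and rose by 0.56 (limma's camera, adjusted p = 0.0274).

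Without the dye-swapped array of replicate 2 the calls of SigB (relative median 0.24, adjusted p = 0.0734), SigM (0.28, adjusted p = 0.0524) and wall teichoic acid genes (0.35, adjusted p = 0.0835) were lost. Without members of another list the SigX, SigM and teichoic acid calls were lost (adjusted p = 0.159 for each), the highest for these 3 lists over the alternatives apart from the estimated correlation, and the lowest were 0.000992, 0.00855 and 0.00639. The lowest for SigB was 0.000992. The SigM call was also lost without genes at the lowest ratio or 0 (adjusted p = 0.0570), and the teichoic acid call against random lists (adjusted p = 0.0542) and after quantile normalization (adjusted p = 0.0896).

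**Figure D2:**
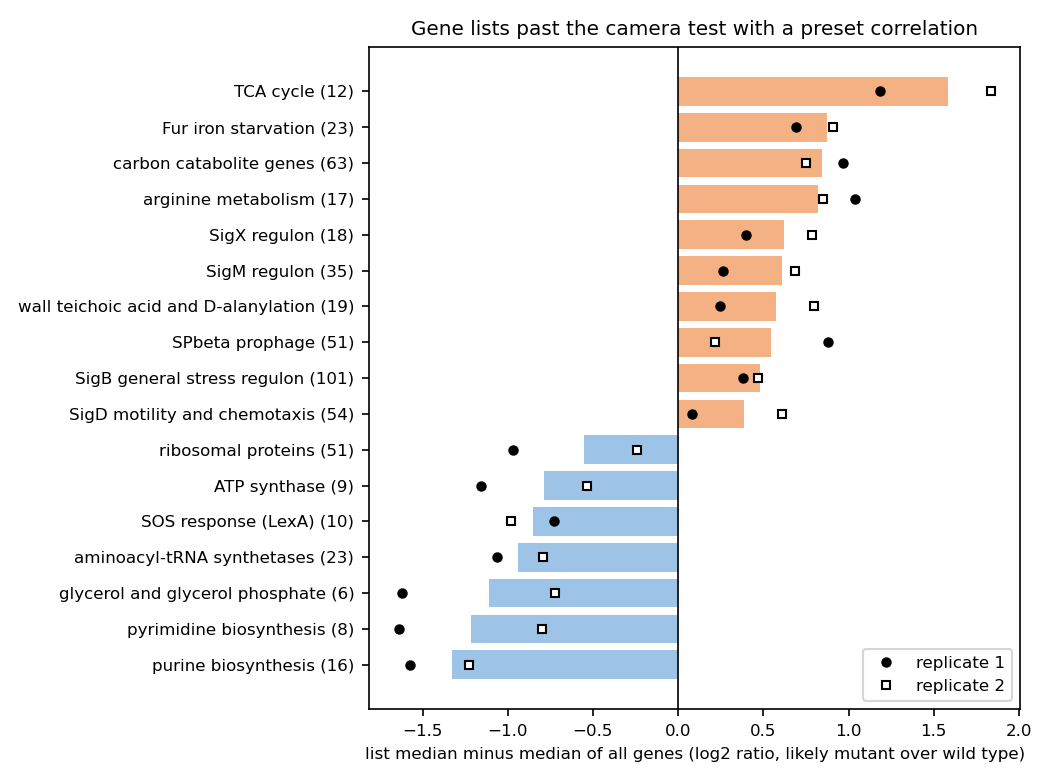
Median log2 ratio of each list minus the median of all genes (x axis, likely mutant over wild type) for the 17 lists past camera at a preset correlation; bars are computed on the means of both replicates, circles replicate 1, squares replicate 2, and brackets hold the number of genes measured. Both replicates lie on the same side of 0 for each list, from 1.59 for the TCA cycle to -1.33 for purine biosynthesis.

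The remaining 21 lists did not pass. Relative medians of growth and metabolism lists were -0.04 for glycolysis (adjusted p = 0.0697), -0.43 for RNA polymerase and sigma factors (adjusted p = 0.0699), -0.51 for fatty acid synthesis (adjusted p = 0.159), -0.28 for respiration and -0.27 for histidine and tryptophan biosynthesis (adjusted p = 0.407 for both). For branched-chain amino acids the value was 0.11 (adjusted p = 0.958), and for methionine and cysteine -0.0094 (adjusted p = 0.897). Without the dye-swapped array of replicate 2, glycolysis passed downward (-0.33, adjusted p = 0.00233), as did RNA polymerase (-0.54, adjusted p = 0.0142) and PerR (-0.32, adjusted p = 0.0330), whose highest adjusted p over the alternatives apart from the estimated correlation were 0.981, 0.363 and 0.993. With each array centred on its median, SigH passed upward (0.58, adjusted p = 0.0355), and its highest adjusted p apart from the estimated correlation was 0.199. Other settings also added lists to the 17 called. With a dye term 18 lists passed, 16 of them among the 17. Without genes at the lowest ratio or 0, 16 lists passed, 15 of them among the 17. Stress and regulator lists stood at 0.58 for SigH (adjusted p = 0.0539), 0.00073 for SigW (adjusted p = 0.569), 0.0097 for the PerR peroxide list (adjusted p = 0.159), 0.22 for HrcA and CtsR heat shock genes (adjusted p = 0.980) and -0.42 for the LiaRS and Bce-type antibiotic response (adjusted p = 0.150). Cell envelope lists stood at 0.27 for peptidoglycan synthesis (adjusted p = 0.233), 0.35 for cell shape and division (adjusted p = 0.227) and 0.15 for autolysins and WalR targets (adjusted p = 0.781). Lists of development and secretion stood at 0.37 for competence (adjusted p = 0.509), -0.39 for early sporulation (adjusted p = 0.509), -0.40 for biofilm matrix (adjusted p = 0.659), 0.29 for surfactin and bacillaene (adjusted p = 0.569), 0.04 for secreted proteases (adjusted p = 0.958) and -0.14 for the PBSX prophage (adjusted p = 0.607). In 5 of these lists, PerR, surfactin, SigW, biofilm matrix and methionine, the median, the mean and the test differed in sign. The relative medians of replicates 1 and 2 had opposite signs in 8 lists, glycolysis (-0.44 and 0.23), PerR (-0.34 and 0.25), SigW (-0.14 and 0.17), surfactin (0.39 and -0.35), biofilm matrix (0.06 and -0.84), methionine (0.11 and -0.19), branched-chain amino acids (-0.25 and 0.37) and heat shock (-0.13 and 0.47). The LiaRS and Bce-type value covers only *yxdJ*, *yxdK*, *yxdL* and *yxdM*, 4 of 18 symbols. The biofilm matrix value covers only *sipW*, *tasA*, *sinR* and *sinI*, 4 of 22. Matched by older symbols, the LiaRS and Bce-type list had a relative median of -0.58 over 18 genes (limma's camera, adjusted p = 0.0805). Biofilm matrix then had -0.33 over 21 genes (limma's camera, adjusted p = 0.280).

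The third question was how far the arrays bore each other out, since each RNA preparation was hybridised in both dye orientations. Across genes, which are not independent replicates, the replicate means correlated with Pearson's r = 0.490 and Spearman's rho = 0.501. Arrays of the same RNA with dyes swapped correlated less (r = 0.0666 in replicate 1 and 0.120 in replicate 2) than arrays of different RNA in the same orientation (r = 0.541 for the direct and 0.434 for the dye-swapped pair). Over the 3044 genes with no value at the lowest ratio or 0, the mean r was 0.305 for the same RNA and 0.567 for the same orientation. The dye-swapped array of replicate 2 had 936 genes below -3 on the log2 scale and 276 at the lowest ratio, against 92 to 380 and 7 to 78 on the other arrays.

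**Figure D3:**
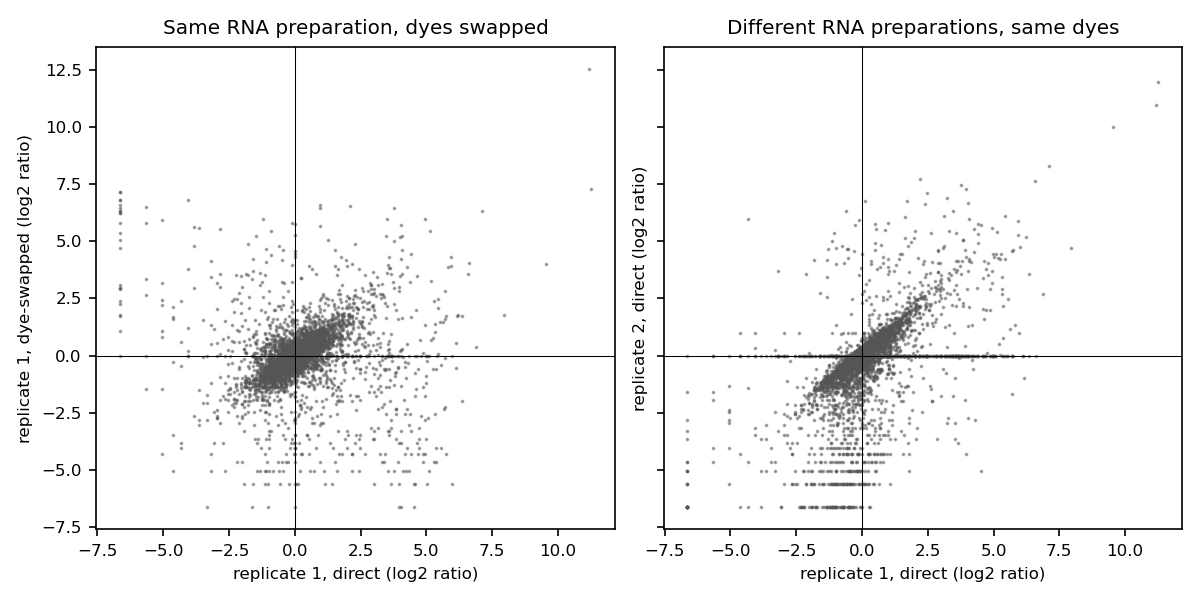
Log2 ratio of each gene on 2 arrays (both axes), for 1 RNA preparation with dyes swapped (left, r = 0.0666) and for both RNA preparations on direct arrays (right, r = 0.541); each point is a gene. Points in lines at 0 and at the lowest values are genes whose ratio stands at 0 on the log2 scale or near the lowest ratio, 0.01.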

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

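Of the tests in this part, those of dye bias, dye-dependent background, abundance scaling, noise in the *roc* genes, SigL raising all its genes alike and SigL without 1 array were chosen after the result was seen, while those of values at the lowest ratio or 0, of the dye-swapped array of replicate 2 and of the SigL list were written before their own results, though after the data had been seen. What would count against abundance scaling was restated after its first result, which had been read as arguing against it, and the test of noise replaced 2 that ran on the *roc* genes alone. A result is given here when 1 of its 4 array values stood apart from the others by more than Dixon's test allows. This held for 14 of 128 results, where chance gives about 1 in 20 or 6.4 for results not picked by their values. Many of the 128 are genes named for a large mean, which 1 outlying array can produce. The 6.4 is therefore not the count to expect here. The array standing apart was the dye-swapped array of replicate 2 in 12 and the direct array of replicate 2 in 2.

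The dye-swapped array of replicate 2 had a median log2 ratio of -0.45 where the others lay between 0 and 0.04. On it the early sporulation list had a median of -2.51 relative to all genes, against 0 to 0.23 on the others, and the autolysin list -0.54, against 0.10 to 0.19. The gene *sigA* stood at 0.057 on it, against -0.18 to -0.17, and *yjbC* at 1.95, against 1.34 to 1.42. The genes *valS* (-3.64), *pbuG* (-6.64), *cheC* (-6.64), *yhdL* (-5.64), *murF* (-6.64) and *uvrC* (-6.64) were lower on it than on any other array, and *yhdK* (5.38) was higher. On the direct array of replicate 2, *rbsA* stood at 3.66, against 2.90 to 2.93, and *yfhO* at -5.06, against -0.03 to 0.83.

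Arrays of one dye orientation correlated more than arrays of one RNA preparation. Values at the lowest ratio or 0 do not account for all of it. With them the mean r was 0.0934 within one RNA and 0.487 within one orientation. Without them it was 0.305 and 0.567, a difference of -0.26. Ratios just above the lowest were kept, so dim spots as such are not excluded. A dye bias that belongs to each probe cannot be told apart from other causes: the differences between dye-swapped and direct arrays correlated between the replicates with r = 0.461 across genes, but this follows from the correlations themselves. Dye-dependent background of dim spots stays open too, as the smallest of the 4 direct minus dye-swapped medians was 0.37. Relative to all genes, the control lines differed by 1.63 and 0.37 and early sporulation genes by 0.45 and 3.09 in replicates 1 and 2. The control lines BMV-RNA2, *yacF*, *yciC* and *yfiF* stood at 0 on all 4 arrays, which draws the control medians towards 0. Other control lines had large ratios. For *lacZ* they were 2.17 and 0 in replicate 1 and 0 and -5.06 in replicate 2, direct array first. Among control lines with values, only *yjcG* was lower on a direct than on its dye-swapped array (-2.00 and -1.79 in replicate 2). No biological explanation was tested, because both arrays of a pair hold the same RNA.

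Ribosomal protein genes lay below other genes. Dim spots of the dye-swapped array of replicate 2 are argued against, since the relative median without it was -0.72. A scaling of ratios that depends on abundance was looked for in 34 genes of other abundant proteins. Their relative median was 0.054, and they went both ways with an SD of 0.88 over the genes. A bootstrap over these genes, taken as independent, gave an interval of -0.29 to 0.81 for that median. The interval lies above the -0.55 of ribosomal protein genes, which argues against an equal shift of all abundant genes. A scaling that varies with abundance cannot be told apart, because spot intensities were not used. A lower level of these transcripts in the mutant remains a hypothesis, and normalization by the authors and growth rate were not tested.

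Arginine breakdown genes held 5 of the 12 highest means. Noise of dim spots is argued against. Of the 17 genes of the arginine list, fixed beforehand, 6 stood at 2 or above on all 4 arrays and 0 others as far from 0. Noise that is independent between the orientations would give 0.0965, estimated from 46 genes whose orientations opposed each other. No other of the 38 lists had more than 3. These genes are read by RNA polymerase with SigL. A higher activity of that polymerase that raises all its genes alike is argued against. The median of the 16 other SigL-read genes minus that of 7 structural *roc* genes was -6.29 (SD over the genes 1.01 and 3.51). These 7 include *rocC*, which did not pass adjusted over the list alone. A higher activity that acts only where a gene's own activator does might raise the *roc* genes and cannot be told apart from a change specific to *roc*. The 16 genes had a relative median of 0.26 (limma's camera, adjusted p = 0.941) with 0 positive and 5 negative on all arrays. *acoC* stood at 3.04 ± 1.30 with 1 array at 0 and *bkdAB* at -0.43 ± 0.11 (SD, n = 2). The count of 0 positive rests on the dye-swapped array of replicate 2. *acoA*, *acoB*, *acoC*, *acoL*, *levE*, *levF* and *sacC* were negative or 0 on it and positive on every other array. Without the dye-swapped array of replicate 2 the relative median was -0.013 (limma's camera, adjusted p = 0.571), and a difference in arginine supply or growth between the cultures was not tested.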

How the results depend on the processing

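Of the settings below, leaving out genes at the lowest ratio or 0, leaving out the dye-swapped array of replicate 2, older symbols and the replicate block without a dye term were chosen after the data were seen; unless said otherwise, the cause was not tested. The 17 lists past camera kept their direction under every alternative run. The limma count of 0 genes became 489 with the 4 arrays as independent (284 higher, 205 lower), 306 with a dye term (180 higher, 126 lower), 752 with the replicate block and no dye term (correlation -0.246) and 480 after quantile normalization (135 higher, 345 lower); the first 3 take arrays of 1 RNA as separate samples. The share of higher calls was 28.1% after quantile normalization against 58.8% with the dye term. A count by size and sign alone gave 789, and the other alternatives kept 0. With an estimated correlation 0 lists passed, but that test rests on 1 residual degree of freedom and hardly any list could pass it. No paired analysis was possible because each array holds both strains and there is 1 group; the planned block with a dye term could not be fitted to 4 arrays, and no gene had more than 1 probe to test on its own.

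The correlation of the replicates, 0.490, became 0.527 with arrays scaled alike, 0.573 after quantile normalization, 0.541 on direct and 0.434 on dye-swapped arrays, and 0.592 without genes at the lowest ratio or 0. The 280 genes at 1 or more became 533 on direct arrays and 81 with the sign of replicate 2 turned, which removes shared effects; the 509 at -1 or less became 957 on dye-swapped arrays and 3 with the sign turned. Leaving out a replicate in turn gave 300 to 495 higher and 385 to 882 lower genes.

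Signs turned for 5 named genes when a replicate or the dye-swapped array of replicate 2 was left out, with ranges of -4.85 to 0.30 for *yxkO*, -2.33 to 0.40 for *yfhO*, -3.39 to 0.11 for *cheC*, -3.22 to 0.13 for *murF* and -0.21 to 2.69 for *yhdK*. Without that array alone *murF* was 0.13 and *yhdK* -0.10, on direct arrays *murF* was 0.12 and *yhdK* -0.21, and on dye-swapped arrays *yfhO* was 0.65. Lists that turned had not passed. Leaving out a replicate or that array gave -0.13 to 0.47 for the heat shock list (-0.0065 without the array), -0.19 to 0.13 for methionine, -0.25 to 0.37 for branched-chain amino acids (-0.050 without the array) and -0.98 to 0.13 for sporulation. The heat shock test also turned with a dye term (0.22) and without genes at the lowest ratio or 0 (0.035), methionine on centring (-0.0094) and quantile normalization (0.23), and branched-chain amino acids on quantile normalization (0.045). Biofilm matrix turned on quantile normalization (-0.34), against random lists (-0.40) and with older symbols (-0.33), SigW (0.00073) and PerR (0.0097) against random lists, and secreted proteases without members of another list (0.043) and without genes at the lowest ratio or 0 (-0.070). Leaving out a replicate also changed the sign of the relative median for glycolysis (-0.44 to 0.23), PerR (-0.34 to 0.25), SigW (-0.14 to 0.17), surfactin (-0.35 to 0.39) and biofilm matrix (-0.84 to 0.06). Where the relative median kept its sign, the direction of the test had turned.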

Other observations

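The tests of the nitrogen and phosphate lists, and the ranking used here, by the array value nearest 0, were chosen after the result was seen. On that ranking 51 genes were at 2 or above and 21 at -2 or below on all 4 arrays. As far from 0 were 46 genes with opposed orientations and 0 with opposed replicates. If the orientations were independent of each other, the 46 would point to 23 genes in each direction, which the lower genes do not exceed. A dye bias could give the 46 genes as well as noise, so this does not show that the lower genes are noise. Genes at 2 or above that were not yet named, chosen after their values were seen, included *ald* (alanine dehydrogenase) at 3.29 ± 0.09, *ysbA* and *ysbB* at 3.71 ± 0.03 and 3.61 ± 0.10, *yvfH* at 3.53 ± 0.06, the acetoin utilisation genes *acuA* and *acuB* at 2.56 ± 0.14 and 2.94 ± 0.06, and *ysfC* and *ysfE*, neighbours of *ysfD*, at 3.98 ± 0.13 and 2.77 ± 0.12 (SD, n = 2 for each). Those at -2 or below included *mntH* (manganese uptake) at -2.85 ± 0.07, *pps* at -2.77 ± 0.11, *yhcA* at -3.34 ± 0.15 and *alsD* (acetoin synthesis) at -4.21 ± 2.03, the last with 1 array at the lowest ratio. None of them passed the limma test over all genes.

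The glutamine transport gene *glnM* (3.72 ± 0.63) and the phosphate transport gene *pstBB* (3.48 ± 0.22) were also among the highest (SD, n = 2). Other genes of the same transporters did not all follow. For phosphate, *pstS* stood at 0.50 ± 0.41, *pstC* at -1.40 ± 0.42, *pstA* at -0.15 ± 0.41 and *pstBA* at -0.14 ± 0.56. For glutamine, *glnP* stood at 2.69 ± 1.24, *glnQ* at 1.10 ± 0.21 and *glnH* at -1.02 ± 2.55. A hypothesis that nitrogen limitation genes of TnrA and GlnR rise as a set was tested on 34 genes: their relative median was -0.019 and limma's camera gave an adjusted p = 0.900 over 3 such lists, with 7 positive and 7 negative on all arrays, so the set may or may not have moved. For 20 phosphate limitation genes of PhoP the relative median was 0.34 with an adjusted p = 0.477, with 3 positive and 3 negative on all arrays; *tuaC* stood at 1.92 ± 0.19 and *pstC* at -1.40 ± 0.42. Without the dye-swapped array of replicate 2 the relative medians were -0.20 and 0.37 (limma's camera, adjusted p = 0.988 and 0.215). Neither hypothesis is decided by these values, and what would count against each was restated after its first result, because a median near 0 with members on both sides decides nothing.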
